A study of Homo sapiens with 6 samples.

How the data were processed

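The series measured RNA bound by G4PID, a biotin ligase directed to G-quadruplexes and pulled down with an anti-HA antibody, and by SF3B4 in HEK293T cells, with 2 eCLIP libraries per antibody and 2 input libraries. Per the labels' protocols, cells were transfected with a plasmid for the ligase or for the untargeted ligase and labelled with 500 µM biotin for 30 min. That text is shared by all samples, so whether the SF3B4 and input cells were transfected and labelled is not settled by it. The labels give no library of the untargeted ligase, and such a control was not analysed here. Nothing in the labels says whether the 2 libraries of a group came from separate cultures or were technical repeats.

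Per the submitters' processing notes, cutadapt 3.4 and STAR 2.7.0d were used, and the builds hg19 and hg38 are listed. The peak caller, its filters, the handling of multiply mapping reads, the use of molecular identifiers and the joining of the 2 replicates are not given in the sources used here. The authors deposited 1 peak list per antibody with chromosome, start, end, 2 values and strand, and no header. The first value was read as the −log10 p-value of the peak and the second as its log2 fold over input, as deposited by the authors. This reading rests on the column order usual for eCLIP peaks and on the values: every first value was above 5 with a maximum of 400, and every second value was above 3. The most frequent first value, 15.7, was shared by 29 G4PID and 300 SF3B4 peaks, and the maximum of 400 by 19 and 15. With 1 list per antibody, peaks were treated as called over both libraries. Input libraries entered only through the authors' values, and fold was used only to describe, rank or filter peaks within a list. Because the lists contain only peaks that passed the authors' thresholds, a gene with no peak is not shown to be unbound.

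Positions were compared with the GENCODE release 29 annotation of the same build. A peak was assigned to the gene of its strand that held its midpoint, protein-coding before other types and exon before intron. 1 peak of 270 for G4PID and 0 of 3660 for SF3B4 had no such gene. Region classes came from the basic transcript set, with coding sequence before UTR, noncoding exon and intron, and intron within 500 nt of a splice site called proximal. No genome sequence was used here. Sequence was rebuilt from the annotated transcripts: 206694 transcripts were laid on the genome with 0 length mismatches and 0 disagreeing bases, so an intron could be searched only where another transcript, such as a retained-intron form, covered it. Windows with any unknown base were left out, which kept 59.6% of G4PID and 41.8% of SF3B4 peaks with 50 nt flanks, but 22.3% and 38.4% of the intronic ones.

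A quadruplex motif was 4 runs of at least 3 G separated by 1 to 7 nt. The expected share came from all searchable windows of the same width in the same gene and region class, with 10000 draws and a two-sided p whose smallest value is 0.0002. Sense and antisense were compared with an exact binomial sign test and the lists with Fisher's exact test. For splice sites, the share of midpoints 10 to 60 nt upstream of the nearest 3' splice site was set against random positions of the same gene, and as an alternative against those of the same gene and region class. For overlap, SF3B4 peaks were moved within their gene and region class. Splice sites with and without an SF3B4 peak were compared within genes by a Cochran-Mantel-Haenszel test and by permuting the label. Genes in both lists and 10 fixed gene lists were tested against 19940 protein-coding genes with Fisher's exact test and Benjamini-Hochberg adjustment. Peaks and genes are the units of these tests, not replicates. Wilson intervals cover counting error only. Computations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.

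The main tests, 10 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives added later are named in the closing section. The rule took the 15 genes whose highest peak ranks first by the authors' fold in each list, up to 15 genes where peaks of both lists overlap, and the members of the 10 lists, by count with 2 to 4 highest members. Genes with the most peaks, motif carriers, the leading genes shared by both lists and a 22-gene list of YAP and TAZ targets used in the closing observations were chosen after their values were seen. Structural RNAs were counted by annotated type or symbol. Fisher's exact tests of 10 structural RNA classes between the lists, and the comparisons of retained introns and snoRNA host genes, were added after the data were examined. On 40 simulated sets of 150 peaks in 300 genes without any effect, the motif test passed the 0.05 threshold in 2 sets, the splice site test in 0 and its form matched on region class in 4, the overlap test in 0, and the stratified test in 2. With an effect planted in 20% of peaks each of these tests passed in 40 of 40 sets. The motif and overlap tests were simulated with positions of the same gene, without the match on region class used in their main form. Smaller effects, and peaks clustered in few genes, were not simulated. The simulations therefore do not show that a small excess would have been detected. The alternatives covered the motif definition, flanks and background, the overlap rule, the background genes, the choice of transcripts, the splice site window and a stricter threshold on the authors' fold.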

Results

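RNA bound by 2 proteins was mapped in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, by eCLIP, in which a protein is immunoprecipitated together with the RNA it contacts and the recovered fragments are compared with an input library. The first protein, G4PID, is an artificial biotin ligase directed to G-quadruplexes, the four-stranded folds that guanine-rich nucleic acids can form. It was expressed from a transfected plasmid and pulled down with an antibody against the HA tag. The second, SF3B4, is a subunit of the SF3b complex of the U2 small nuclear ribonucleoprotein, which recognises the branch point region of introns, and was pulled down with an antibody against SF3B4 itself. The series held 6 libraries, 2 each for G4PID, SF3B4 and input. The deposited data analysed here were 1 peak list per antibody, with no value per library, so the spread between replicates could not be measured, the read depth is unknown, and every p-value below describes peaks or genes of these lists. All coordinates are on hg38.

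The G4PID list held 270 peaks in 127 genes, and 28 genes with 3 or more peaks carried 154 of them (57.0%). The 2 nuclear long noncoding RNAs NEAT1, the scaffold of paraspeckles, and MALAT1, a resident of nuclear speckles, had 16 and 14 peaks. DHRS2, which encodes a short-chain dehydrogenase, had 15 peaks, and PLEC, which encodes the cytoskeletal linker plectin, had 14. The SF3B4 list held 3660 peaks in 1884 genes. Its genes with the most peaks were FANCA, a Fanconi anaemia DNA repair gene with 18 peaks, CAD, the multifunctional enzyme of pyrimidine synthesis with 12, PCNX3 with 12, and DGCR8, HNRNPH1 and HNRNPU with 11 each. DGCR8 encodes a partner of Drosha in microRNA processing, and the other two encode heterogeneous nuclear ribonucleoproteins. The authors' value per peak, read as log2 fold over input from the order and range of the columns, had a median of 4.92 and a maximum of 9.97 in the G4PID list. In the SF3B4 list the median was 3.93 and the maximum 7.60, and no value in either list was below 3. Whether the input came from the same transfected cultures as the G4PID libraries is not settled by the labels, so a fold over input was not separated from a difference in RNA amount. Peaks were 61 nt wide at the median for G4PID and 71 nt for SF3B4. The same pair of fold and p was shared by 2 or more peaks for 61.9% of G4PID and 88.5% of SF3B4 peaks.

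Ranked by the authors' fold, the G4PID list was led by MTRNR2L1, a nuclear gene that resembles mitochondrial 16S ribosomal RNA (log2 fold 9.97, chromosome 17, 22524409 to 22524478, 3'UTR). Mitochondrial 16S ribosomal RNA itself, from MT-RNR2, also had a G4PID peak (log2 fold 3.20). How reads that match both were assigned is not given in the sources used here. MMP3, which encodes the matrix metalloproteinase stromelysin, came next (5 peaks, highest log2 fold 7.71). NEAT1 followed with its highest peak at 7.52. All 16 NEAT1 peaks lay between positions 65422818 and 65426472 of chromosome 11, within the first 3699 nt of a gene annotated over 22767 nt. The 15 DHRS2 peaks, at log2 folds from 5.39 to 7.10, comprised 6 in coding sequence, 1 in the 3'UTR and 8 in introns. Other genes among the 15 highest were MIR663AHG (7.32), FOSL1, which encodes a Fos-family transcription factor (6.86), GCNT1 (6.61), the pseudogene CYP4F32P (6.57), FLNC, which encodes an actin-binding filamin (6.43), PTPRN2 (6.39), ZFP36L1, which encodes an RNA-decay factor (6.39), TCF25 (6.35) and CYR61, which encodes a matricellular protein (6.17). The remaining ones were 2 long noncoding RNA genes, AC012617.1 (6.30) and FP236383.1 (6.26), the latter within a copy of the 45S ribosomal RNA precursor.

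**Figure D1:**
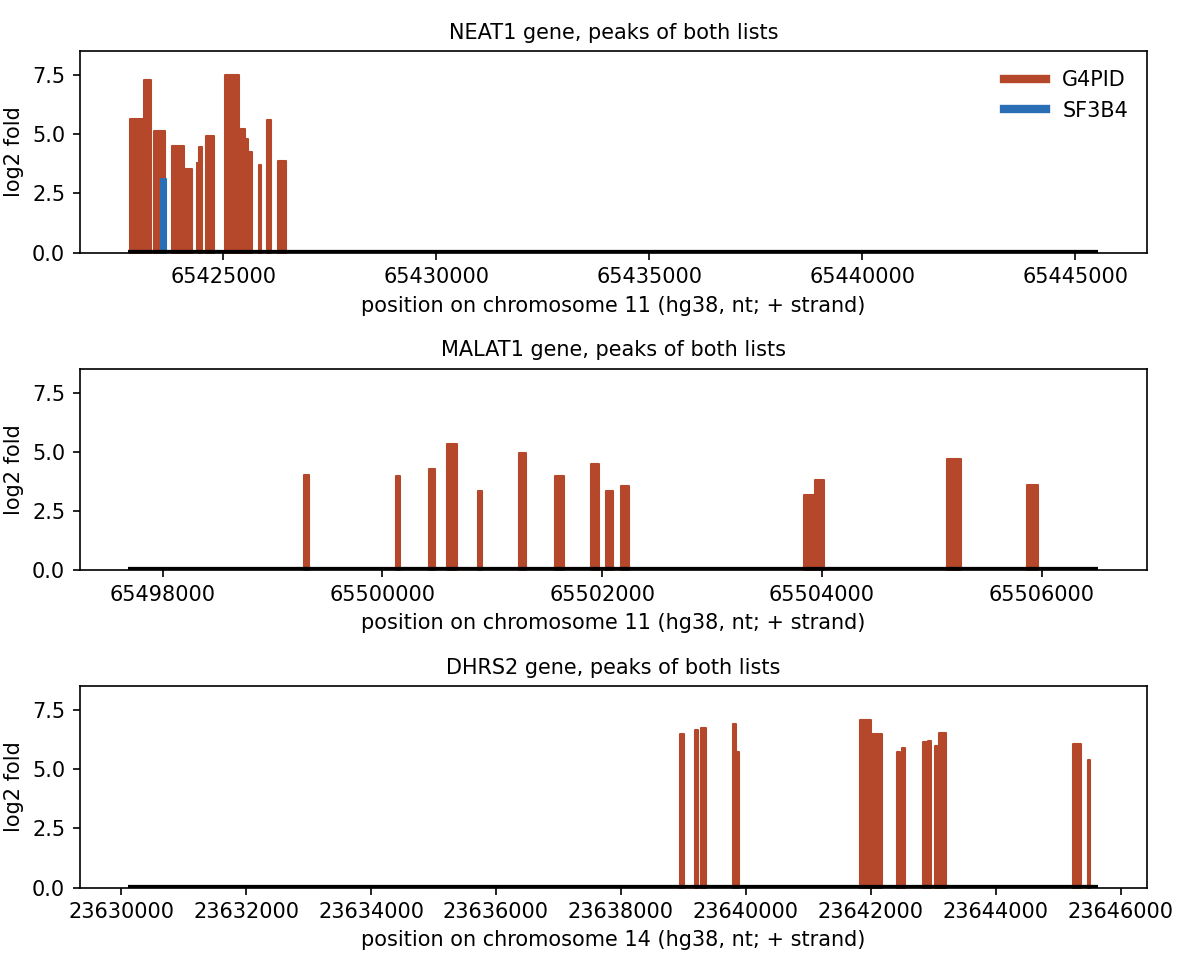
Peaks of both lists along NEAT1, MALAT1 and DHRS2; the horizontal axis is the hg38 position in nt, the black line the annotated gene, and each bar a peak drawn over its own width to the height of the authors' log2 fold. The 16 G4PID peaks of NEAT1 end at 3699 nt from the gene start, whereas the 14 of MALAT1 reach 8279 nt into a gene of 8829 nt.

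The SF3B4 ranking was led by a U2 small nuclear RNA copy, RNU2-70P (log2 fold 7.60, chromosome 1, 236267861 to 236267889). A second copy, RNU2-4P, stood at 7.07, and the peaks that ranked CCDC200 (6.91) and RUVBL1 (6.65) overlapped U2 copies within those genes. Splice-site peaks led in HNRNPH1 (7.13), in EEF1A1, which encodes the elongation factor that delivers aminoacyl-tRNA (6.96), in EIF4A1, which encodes a helicase of translation initiation (6.85), and in RABGGTB (6.76). The HNRNPH1 peak at 179614967 to 179615012 on chromosome 5 had its midpoint 30 nt upstream of a 3' splice site. HNRNPU (6.68), METTL17 (6.65), RAD54L (6.65), and the ribosomal protein genes RPL6 (6.65) and RPL17 (6.53) were also among the 15 highest. Single peaks far from any splice site ranked AC024901.1 (7.26) and EEPD1 (6.81). U2 copies are near-identical, so reads assigned to any 1 of them may belong to another.

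The 2 proteins occupied different parts of their target RNAs. Proximal intron, within 500 nt of a splice site, held 84.9% of SF3B4 peaks (95% Wilson interval 83.7 to 86.0%) and 13.3% of G4PID peaks (9.79 to 17.9%). G4PID peaks were spread over coding sequence (64 peaks, 23.7%), distal intron (67, 24.8%), 3'UTR (43, 15.9%), exons of noncoding RNA (38, 14.1%) and 5'UTR (21, 7.78%). Each of those 5 classes held under 5% of SF3B4 peaks. The odds of a proximal intronic peak were 36.4 times higher for SF3B4 (Fisher's exact test, two-sided, adjusted p = 2.03e-134, Benjamini-Hochberg over 9 classes and sums of classes). Over all introns, 88.5% of SF3B4 and 38.1% of G4PID peaks were intronic (odds ratio 12.4, adjusted p = 3.11e-76, same exact test). With retained-intron transcripts counted as exons, proximal intron held 49.1% of SF3B4 and 9.26% of G4PID peaks (odds ratio 9.44), all introns held 50.5% and 30.0% (odds ratio 2.38), and the difference in noncoding exon turned around (odds ratio 0.128 before and 1.97 after, adjusted exact p = 3.96e-06). With 1 peak per gene the odds ratio for proximal intron was 23.0, and with intron counted before exon that for all introns was 19.4.

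**Figure D2:**
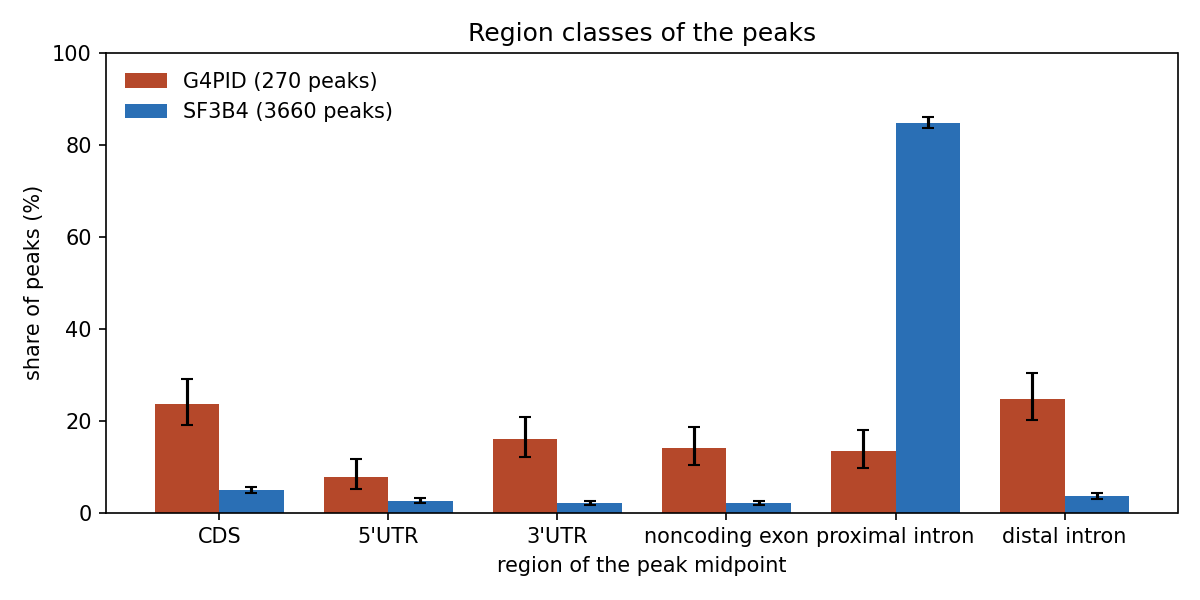
Share of the peaks of each list (vertical axis, percent) in each annotated region (horizontal axis), with 95% Wilson intervals as error bars. The SF3B4 bar for proximal intron stands at 84.9%, and the tallest G4PID bar, for distal intron, at 24.8%.

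SF3B4 peaks gathered immediately upstream of 3' splice sites, as in RPL17 (midpoint 29 nt upstream), EEF1A1 (31 nt), RABGGTB (32 nt), RPL6 (37 nt) and RAD54L (42 nt). Of 3623 SF3B4 peaks in genes with an annotated 3' splice site, 2496 (68.9%, 95% Wilson interval 67.4 to 70.4%) had their midpoint 10 to 60 nt upstream of the nearest site. Random positions of the same genes gave 4.05%, a 17.0-fold difference (permutation test with 10000 draws, two-sided, p = 0.0002, the smallest it can give). Random positions of the same gene and region class gave 9.20%, a 7.49-fold difference (same permutation p). Among SF3B4 peaks within 1000 nt of a site the median distance was -30 nt, with quartiles of -41 and -16 nt. For G4PID, 7 of 257 peaks (2.72%) fell in that stretch against 2.66% at random positions (permutation p = 1). The difference between the lists gave an odds ratio of 79.1 (Fisher's exact test, two-sided, p = 4.19e-108). On the exon side of 5' splice sites, 16 G4PID peaks (6.23%) lay 10 to 60 nt upstream, against 2.74% at random positions of the same genes (permutation test, two-sided, p = 0.005) but 6.15% at random positions of the same region class (permutation p = 1).

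**Figure D3:**
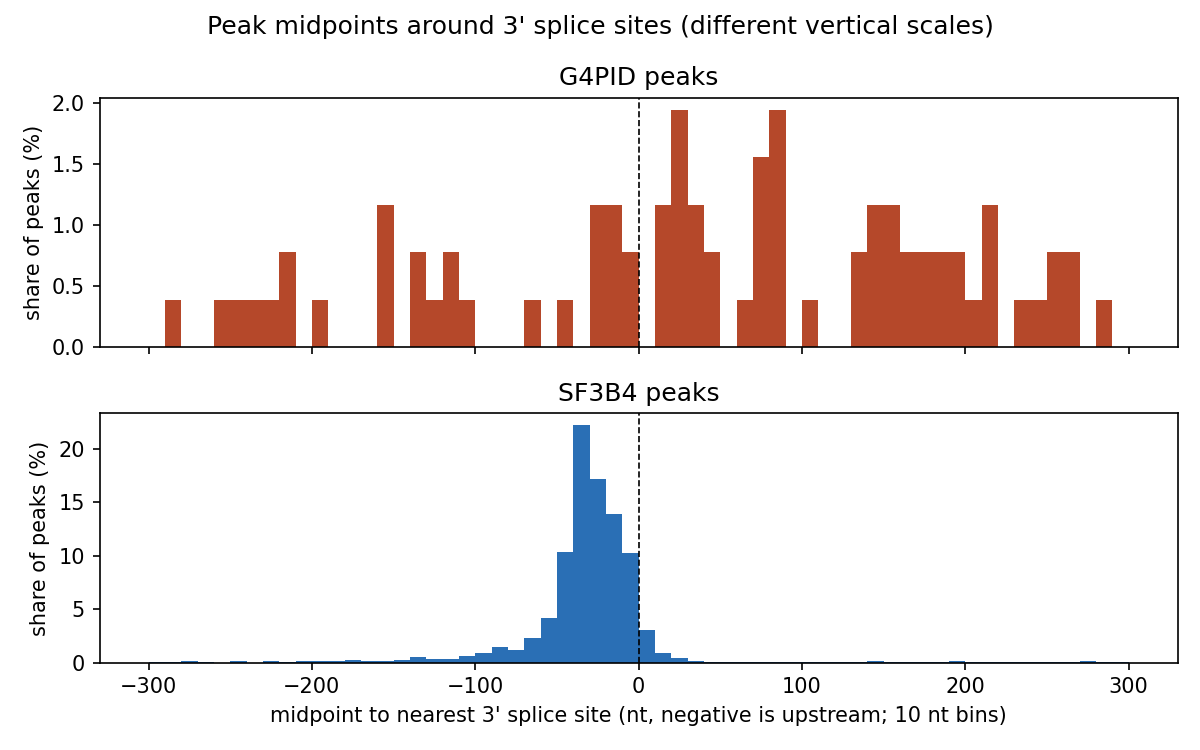
Distance of peak midpoints to the nearest 3' splice site (horizontal axis, nt, negative upstream, bins of 10 nt) against the share of peaks of each list (vertical axis, percent, on a different scale in each panel). SF3B4 peaks pile up upstream of the site, around a median of -30 nt, and G4PID peaks show no such cluster, with 7 of 257 between 10 and 60 nt upstream.

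Whether RNA contacted by the quadruplex-directed ligase carries quadruplex motifs was asked next. A motif of 4 runs of at least 3 G with loops of 1 to 7 nt was found in sense in 9 of 161 searchable G4PID windows, in FOSL2 (5'UTR), PTPN12 (5'UTR), SLC1A5 (coding), ERF (coding), SLC12A4 (3'UTR), SNRNP70 (intron), NEAT1, and at 2 places in MAFK. The NEAT1 motif, GGGAAGGGGATGGGGATTGTGGG, lay at 65426023 to 65426045 on the plus strand of chromosome 11, across the upstream edge of a peak (65426031 to 65426116) with a log2 fold of 5.59. The FOSL2 motif, GGGAAGGGGTGCGGGTCTGGG, lay at 28393014 to 28393034 on the plus strand of chromosome 2. Of these 9 motifs, the shortest match in each window, 0 lay wholly within the deposited peak. Its edge was crossed by 7, and 2, in SNRNP70 and PTPN12, lay in the flank alone. The share of 5.59% (95% Wilson interval 2.97 to 10.3%) did not differ detectably from the 4.22% of windows matched on gene and region (ratio 1.33, permutation test with 10000 draws, two-sided, p = 0.414). The antisense strand of the same windows held the motif in 17 cases (exact binomial sign test against sense, two-sided, p = 0.169), but that test ignores that matched windows also held it more often in antisense, 11.7 expected against 6.79 in sense, and against these the antisense ratio was 1.45 (permutation p = 0.0866). Without flanks, 189 G4PID peaks as deposited could be searched, more than the 161 above, and any match counted. Of these, 1 held the motif in sense against 2.88 expected from matched windows (permutation p = 0.322) and 13 in antisense against 5.50 (ratio 2.36, permutation p = 0.0028). With loops of 1 to 12 nt the counts were 16 in sense against 11.2 expected from matched windows (permutation p = 0.132) and 30 in antisense against 20.0 (permutation p = 0.0072). The G4Hunter score rates runs of G over 25 nt and counts runs of C against them. At 1.5 or more, 23.6% of G4PID windows passed in sense against 15.4% of matched windows (ratio 1.53, permutation p = 0.001). The antisense strand passed 1.51 times as often as its matched windows (permutation p = 0.0002). Only 22.3% of intronic G4PID peaks could be searched, because intron sequence was known only where a transcript model covered it.

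SF3B4 windows held the motif in sense in 68 of 1529 cases. Of these 68 motifs, again the shortest match in each window, 20 lay wholly within the deposited peak, 29 crossed its edge and 19 lay in the flank alone. Those in the flank alone included VEGFA, which encodes an angiogenic growth factor, and the ribosomal protein gene RPS13. The SF3B4 share of 4.45% (95% Wilson interval 3.52 to 5.60%) did not differ detectably from that of G4PID windows (odds ratio 1.27 for G4PID over SF3B4, Fisher's exact test, two-sided, p = 0.549) or from the 5.15% of matched windows (ratio 0.863, permutation p = 0.186). With 1 peak per gene the shares were 8.96% for G4PID and 3.74% for SF3B4 (odds ratio 2.53, p = 0.0523, same exact test). With the G4Hunter score in sense the lists differed, at 1.5 or more by 23.6% against 12.4% (odds ratio 2.18, p = 0.000231, same exact test). At 1.2 or more they differed by 34.8% against 26.4% (odds ratio 1.49, p = 0.0253, same exact test). The antisense shares went the same way, 30.4% against 16.5% at 1.5 and 39.1% against 32.0% at 1.2, so the difference was not particular to sense. Of the searched windows, 138 of 161 for G4PID but 285 of 1529 for SF3B4 were exonic. The SF3B4 shares of G4Hunter windows lay below those of matched windows (ratio 0.840 at 1.5, permutation p = 0.0026). In antisense, which corresponds to C-rich RNA, the motif stood in 90 windows, 1.37 times the matched value (permutation p = 0.001). Within the peaks as deposited, without flanks, the sense motif was less frequent than in matched windows (1.21% against 2.27%, ratio 0.532, permutation p = 0.0014). Matched windows shared gene and region class but not distance to the splice site. For SF3B4 these differences in sense and antisense were therefore not separated from the position of its peaks upstream of 3' splice sites.

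**Figure D4:**
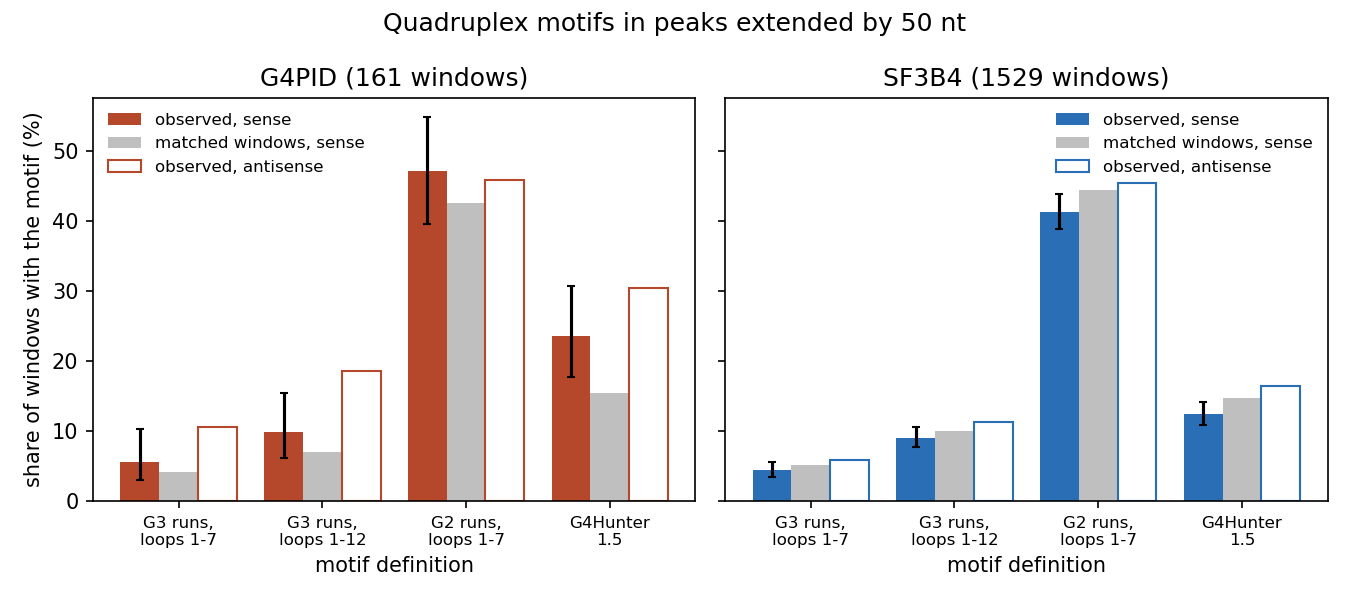
Share of searchable windows that hold a quadruplex motif (vertical axis, percent) under 4 motif definitions (horizontal axis), for sense windows with 95% Wilson intervals, matched windows of the same genes and regions, and the antisense strand. For the G4PID list the observed share under the first definition is 5.59% against 4.22% in matched windows; in antisense it is 10.6%, that is 17 windows, against 11.7 expected from matched windows, which are not drawn for that strand.

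Among the searchable 3' splice sites of genes with an SF3B4 peak, those with a peak within 100 nt carried fewer quadruplex motifs than the others. These genes held 30129 such sites, 3201 of them with a peak, and most could not be searched. Searchable sites are a subset set by the annotation, since intron sequence was known only where a transcript covered it. The motif lay in sense within 100 nt of 46 of 1136 searchable sites with a peak (4.05%) and of 257 of 4372 without one (5.88%). Compared within genes, the Mantel-Haenszel odds ratio was 0.604 (Cochran-Mantel-Haenszel test, p = 0.0111; permutation of the peak label within genes, 10000 draws, two-sided, p = 0.0122). The intron side alone gave 0.649 (permutation p = 0.0168). On the exon side alone, where more sites were searchable, the raw share was higher with a peak (0.619% of 2423 sites against 0.438% of 20544). Within genes the odds ratio there was 0.844 (permutation p = 0.690). With sites matched on GC content in place of gene the odds ratio was 0.725 and no longer passed (permutation p = 0.0648), and windows of 50 and 200 nt gave 0.457 (p = 0.152) and 0.831 (p = 0.366) by the same permutation test.

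G4PID and SF3B4 met in the same genes more often than at the same positions. Of 99 protein-coding genes with a G4PID peak, 21 also had an SF3B4 peak, against 8.79 expected among 19940 protein-coding genes (odds ratio 2.78, Fisher's exact test, two-sided, p = 0.000136). By their G4PID fold they were led by TCF25 (log2 fold 6.35 in the G4PID and 5.69 in the SF3B4 list), PCBP2, which encodes a poly(C)-binding protein (6.07 and 5.05), MROH6 (5.80 and 4.58) and YBX3, which encodes a cold-shock domain protein (5.54 and 5.09). SNRNP70, which encodes a U1 snRNP protein, EIF4A2, RECQL4 and SQSTM1 were among them as well. RNA abundance was not used here, so expressed genes could not be taken as the background. At the level of position, 1 G4PID peak overlapped an SF3B4 peak on the same strand, by 97 nt in NEAT1 (65423390 to 65423638 and 65423542 to 65423662 on chromosome 11). SF3B4 peaks moved within the same gene and region class touched 0.932 G4PID peaks on average (permutation test with 10000 draws, two-sided, p = 1). Peaks within 100 nt of each other added SNRNP70, EIF4A2 and MIR222, for 4 G4PID peaks against 1.77 in the draws (permutation p = 0.218).

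SF3B4 peaks were common in genes for RNA-binding and translation proteins. Ribosomal protein genes had a peak in 66 of 89 cases (odds ratio 30.5, Fisher's exact test, two-sided, p = 2.00e-50, adjusted p = 2.00e-49), led by RPL6 (log2 fold 6.65), RPL17 (6.53) and RPL10 (6.30). SR protein genes, whose products promote exon recognition, had one in 13 of 17 (odds ratio 33.6, adjusted p = 8.69e-11, same exact test), with SRSF5 at 6.51 and SRSF11 at 5.95 over 10 peaks. The hnRNP genes had one in 17 of 24 (odds ratio 25.1), led by HNRNPH1, HNRNPU (6.68) and HNRNPA1 (5.97). Genes for proteins known to bind or unwind G-quadruplexes had one in 19 of 30 (odds ratio 17.9), with EIF4A1 (6.85), DDX5 (6.09) and EWSR1 (5.86) first. Translation factors (13 of 26), abundant housekeeping transcripts (16 of 28) and the SF3b, SF3a and U2 partners of SF3B4 (8 of 20, among them DDX46 at 5.66, SF3B3 at 4.93 and SF3B4 itself at 4.69) passed too. These 7 of the 10 lists passed against all protein-coding genes, of which 8.88% had a peak (Fisher's exact test, two-sided, Benjamini-Hochberg over 10 lists). Histone genes (3 of 91, led by H3F3A at 5.05), transcripts known for RNA quadruplexes (3 of 28, led by EIF4G1 at 5.66) and the control list of genes of other tissues (0 of 28) did not. RNA amount was not measured here and so was not separated from binding. Intron number was not matched in these tests either, although most SF3B4 peaks lay near 3' splice sites. A list with few peaks, such as the histones, is therefore not shown to be avoided. Genes with a peak in either list are no usable background for SF3B4, since 95.8% of them had an SF3B4 peak and even 66 of 66 ribosomal protein genes gave p = 0.111 (Fisher's exact test).

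In the G4PID list, 0 of the same 10 lists passed the adjusted test, and 1 had an unadjusted p under 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg over 10 lists). That list was the quadruplex-binding proteins, with DHX36, a helicase that unwinds quadruplexes (log2 fold 4.61), and EIF4A2 (4.43), 2 of 30 (p = 0.00970, adjusted p = 0.0970, same exact test). The EIF4A2 peak (186786358 to 186786409, chromosome 3) overlapped a snoRNA inside the gene. The DHX36 peak (154324198 to 154324251, minus strand of chromosome 3) covered codons 56 to 73. Whether its reads came from the transfected plasmid is taken up in the closing observations and was not settled. The hnRNP list had PCBP2 (6.07), the translation factors EEF1D (4.39), and the transcripts known for RNA quadruplexes CTSB (4.12) among coding genes, besides the noncoding NEAT1 and MALAT1. Ribosomal protein genes, SR protein genes, histones, housekeeping transcripts, SF3b partners and genes of other tissues had 0 G4PID peaks, where the largest expected number was 0.452.

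Peaks on structural RNAs differed between the lists. U2 snRNA and its copies carried 34 SF3B4 peaks and 0 G4PID peaks, a difference that was not detectable with 270 G4PID peaks (Fisher's exact test, two-sided, p = 0.168, adjusted p = 0.280 over 10 RNA classes). The 45S ribosomal RNA precursor on chromosome 21 had 9 G4PID peaks, at 2 loci, and 0 SF3B4 peaks (adjusted p = 3.01e-10, same exact test). U1 snRNA copies had 4 and 0 (adjusted exact p = 0.000109), and nuclear copies of mitochondrial 16S ribosomal RNA had 3 and 0 (adjusted exact p = 0.00107). Mitochondrially encoded RNA had 1 G4PID peak, in MT-RNR2, and 0 SF3B4 peaks (adjusted exact p = 0.137). These RNAs exist in many near-identical copies, and how the authors assigned reads that match several of them is not given in the sources used here. The exact test counted each peak as independent, although several lay on copies of 1 RNA, so its p-values may be too small.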

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

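Alternatives that use exonic or intronic peaks alone, drop NEAT1, MALAT1 and ribosomal RNA, add retained introns, keep 1 peak per gene in the position and region results, look downstream of 5' splice sites, or draw random positions within the region class were chosen after seeing the data. Of 81 alternatives to the main results, 55 kept direction and side of the threshold, including those for genes in both lists, overlap, and intronic share, whose odds ratios ranged from 9.44 to 47.6 for proximal intron and from 2.38 to 19.4 for all introns; 9 newly passed, 5 no longer passed, 9 turned around and 3 counts moved. At or above the median fold, 144 G4PID and 1834 SF3B4 peaks were left, by construction. For the G4PID motif, G4Hunter at 1.5 gave 23.6% and at 1.2 gave 34.8%, both above matched windows, while no flanks (0.529%), the upper fold range (4.11%) and the opposite strand as background (5.59%) put the share below its comparison without passing, the last of them without allowing for the higher antisense count of matched windows (11.7 against 6.79). For SF3B4, 4 runs of 2 G (41.4%), G4Hunter at 1.5 (12.4%) and at 1.2 (26.4%), and no flanks (1.21%) passed as a deficit, against windows not matched on distance to the splice site. The odds ratio of G4PID over SF3B4 windows passed with G4Hunter at 1.5 (2.18) and at 1.2 (1.49) and turned around without flanks (0.436). The antisense shares at 1.5 differed in the same direction (30.4% against 16.5%). With 1 peak per gene that odds ratio was 2.53 without passing (Fisher's exact test, p = 0.0523). At 5' splice sites, G4PID rose to 6.23% and SF3B4 fell below random positions at 2.62%; 10 to 60 nt downstream of 5' splice sites held 0.389% of G4PID peaks, and 1 peak per gene upstream of 3' splice sites gave 2.61%, both below random positions. Against random positions of the same region class, neither list stood apart upstream of 5' splice sites (G4PID 6.23%, SF3B4 2.62%), and both lay below them downstream (0.389% and 5.02%); for SF3B4 that direction depends on the background, as the 5.02% lay above the 4.11% at random positions of the same genes (permutation p = 0.008). The odds ratio for motifs at 3' splice sites no longer passed at 50 nt (0.457), 200 nt (0.831), on the exon side (0.844) or matched on GC content (0.725). With retained introns, the noncoding exon odds ratio of SF3B4 over G4PID was 1.97. Against genes with a peak in either list, 0 gene lists passed for SF3B4, with 0 at an unadjusted Fisher's exact p under 0.05, by construction, as 95.8% of those genes had an SF3B4 peak; quadruplex-binding proteins (95%) and transcripts known for quadruplexes (75%) lay below that, histones (100%) above. Except where construction shows it, the cause was not tested. Of 66 alternatives for single classes and lists, 56 kept direction and side, 6 no longer passed and 4 turned around. No paired analysis was possible because the lists hold no values per replicate, although the labels number the replicates alike; leaving out each replicate could not be run for the same reason. Unknown read depth limits every share, and 61.9% of G4PID peaks share their fold and p with another peak.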

Other observations

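The tests on retained introns and snoRNA hosts, those on intronic windows and on DHX36, the YAP and TAZ list itself and its length ratio, were chosen only after the data or the result were seen. SF3B4 peaks were more frequent at introns that are annotated as retained in some transcript. In protein-coding genes with an SF3B4 peak, 740 of 3560 introns with a peak at their 3' end (20.8%) were contained in an exon of a retained-intron transcript, against 2276 of 28254 other introns (8.06%). Compared within genes the Mantel-Haenszel odds ratio was 2.40, and within classes of intron length it was 2.97 (permutation test within strata, 10000 draws, two-sided, p = 0.0002 for both, the smallest it can give). Introns with a peak were shorter, with a median of 681 nt against 927 nt. The amount of RNA that still held each intron was not measured, so it was not separated from a preference in binding. Host genes of intronic snoRNAs had SF3B4 peaks in 98 of 256 cases (38.3%), more often than other protein-coding genes (odds ratio 6.68, Fisher's exact test, two-sided, p = 3.63e-38), and without ribosomal protein genes in 73 of 228 (32.0% against 8.32% of the others). Within these 98 genes, introns that hold a snoRNA had a peak in 23.3% of cases and the others in 15.1%, and compared gene by gene no difference was detectable (Mantel-Haenszel odds ratio 0.761, permutation test, two-sided, p = 0.248). Among noncoding genes that host snoRNAs, which were not tested as a group, GAS5 had 9 peaks and SNHG1 had 8.

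The first pattern is that quadruplex motifs in sense were not detectably enriched in windows around G4PID peaks. A motif definition that is too strict may hide an excess: 4 runs of 2 G gave a ratio of 1.11 to matched windows (permutation p = 0.190). The G4Hunter excess at 1.5 appeared in both strands, 1.53 in sense and 1.51 in antisense, so guanine richness of the RNA and general GC richness cannot be told apart there. Most passing windows passed on 1 strand only, 33 in sense and 44 in antisense. At 1.2 the ratios were 1.29 in sense (permutation p = 0.0172) and 1.16 in antisense (permutation p = 0.0774). Motifs farther away could also be missed, and flanks of 100 nt gave a ratio of 1.40 (permutation p = 0.176). Bound motifs might lie in unsearched introns: 2 of 23 searchable intronic windows held one against 7 of 138 exonic windows (Fisher's exact test, two-sided, p = 0.617), too few to decide. All 3 explanations stay open, and no biological explanation was tested, since an untargeted ligase was not analysed here.

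The second pattern is the single G4PID peak in DHX36, with a log2 fold of 4.61 and 0 SF3B4 peaks in that gene. DHX36 binds quadruplexes through a segment of 53 residues that begins at residue 53, and pieces of it have been used to build artificial quadruplex-binding proteins. What the transfected construct contains is not given in the sources used here. All of the peak's 54 bases (100%) encode residues of that segment, from codon 56 to codon 73, whereas 1.59% of the possible positions of a peak of that width in the mRNA would do so. A candidate explanation is therefore that reads came from the plasmid's own transcript rather than from cellular DHX36 RNA, which reads across the construct's junctions could settle; no biological explanation was tested.

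The third pattern is that G4PID genes include targets of YAP and TAZ, the transcriptional coactivators controlled by the Hippo pathway. Of 22 listed genes, 6 had a G4PID peak, CYR61 (log2 fold 6.17), AXL (5.92), ANKRD1 (5.46), CTGF (5.12), GADD45A (4.86) and CRIM1 (4.80), against 0.109 expected among protein-coding genes (Fisher's exact test, two-sided, p = 8.99e-10, on a list drawn up after these genes were seen, so not independent evidence). Tests that count these 6 genes again, against draws matched on exonic length (permutation p = 0.0001) and against SF3B4 genes (Fisher's exact test, p = 1.90e-08), were planned but their outcome was fixed by the choice of the list, so they support nothing here. Matching on exonic length itself raised the expected number only from 0.109 to 0.118 (1.08 times). The G4PID genes differed little in that length from all protein-coding genes, with medians of 3478 and 3160.5 nt. This argues against exonic length as the cause, by a criterion set after the result was seen. Gene length with introns was not matched, so it stays open. Whether any eCLIP library of these cells would call such genes stays open, since SF3B4 genes held 0 of the 22 with 1.95 expected (Fisher's exact test against other protein-coding genes, two-sided, p = 0.255), and RNA that is plentiful in the cells used for G4PID but scarce in the input, whether raised by transfection or by culture conditions, may give the same picture and was not tested, nor was any biological explanation. That limit applies to every G4PID fold over input. It includes AXL, MMP3 (7.71) and, named after their values were seen, KRT81 (5.92), MIR222HG (5.46) and CD44 (5.12), which may not be typical of HEK293T. Their RNA levels were not used here, and whether the input came from the same cells was not tested.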
